A study of Mus musculus with 3 samples.

How the data were processed

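The series holds 3 biological repeats of the R1 mouse ES cell line (strain 129) on the Affymetrix Mouse Gene 1.0 ST array. Total RNA was extracted with Trizol and labelled with biotin by the WT Terminal Labeling Kit, per the labels' protocols. The labels give 1 group, so no comparison between conditions was made. They call the repeats biological and do not describe how the cultures were kept.

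The deposited values are probe set intensities on a linear scale, never negative, as their range shows. GCOS 1.4 is named in the submitters' processing notes. The methods of background correction, normalization and probe set summary are not given in the sources used here, so the scale of a difference may depend on steps that are not known. The arrays' medians lay close together, at 47.8, 46.7 and 46.8, while their sorted values were not identical, and no further normalization was applied in the main setting. No value column was without a sample, and the lower limit of 1 on intensity before taking log2 changed no value.

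Probe sets were named through the platform annotation supplied with the values, which can be old. Of 26730 probe sets, 20764 had 1 gene symbol, 1419 had several and 4547 had none listed; the last 2 kinds were left out of all tests. Gene identifiers of 20678 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for names only, and 86 did not match and kept the annotation's symbol; no symbol changed. Several probe sets of a gene were averaged on the log2 scale (930 genes), leaving 19057 genes. Intensities of different probe sets depend on their probes, so no gene's level was ranked against another's. Coordinates are not printed because the sources used here name no build for the values.

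A gene was called above background on an array when it exceeded the 95th percentile of 1172 olfactory and vomeronasal receptor genes on that array, at log2 4.72, 4.60 and 4.61 (intensities 26.4, 24.3 and 24.4). Of those receptor genes 45 (3.84%) passed on all 3 arrays. Of 17885 genes outside the receptor families 12780 (71.5%) did. The cutoff is a limit of detection: a gene below it was not shown to be silent.

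Gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined. Of 33 lists, 31 had at least 3 measured genes; the Y-linked and X inactivation lists had 0 and were not analysed here. The named genes are, in each list, the first 4 measured members, the member with the largest SD, and every member on the smaller side of the background call where that side held 5 or fewer. Over all genes they are the 10 with the largest SD among those above background on all 3 arrays and the 10 with the smallest adjusted p in the variance test. Other genes named were chosen after their values were seen.

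The share of each list above background on all 3 arrays was set against all other genes outside the receptor families with a two-sided Fisher's exact test (scipy 1.17.1), adjusted by Benjamini-Hochberg over 31 lists. Genes are not independent replicates. The spread between repeats was the SD over 3 arrays. Genes varying beyond the trend were tested with limma 3.58.1 in R 4.3.3: the variance from an intercept-only fit over the trended, robust prior variance was set against the F distribution with 2 and 9.85 degrees of freedom, over 13600 genes above background on at least 1 array, with Benjamini-Hochberg adjustment at 0.05. The spread of a list was its median SD, set against 10000 random lists of the same size matched on mean level in 20 bins. The shift of a repeat was the median over a list of its log2 value minus the mean of the other 2 repeats, given as a percentile of such random lists. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.

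The tests were tried on simulated data first. With 200 of 13600 genes changed on 1 array, the variance test recovered 63% of changes of 1 log2 unit and 100% of changes of 1.5, with 3 false calls among 166. Over 19057 simulated genes, a list of 20 shifted by 0.4 was recovered at 0.38, and 2 of 60 unchanged lists fell outside the middle 95% in the list shift test. The list spread test called 2 of 60 unchanged lists, and the Fisher test 2 of 60 random lists, at an unadjusted p under 0.05. Simulated genes varied independently, and all had the same SD in the list shift and list spread tests. Variances for the variance test were drawn from the kind of distribution that the test assumes. These rates therefore do not cover genes of a pathway that vary together.

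Alternatives were a 99th percentile cutoff, other silent families as background (172 genes), 2 of 3 arrays sufficing, quantile normalization, centring on the median, all genes in place of those above background, the highest probe set of a gene, a prior without robust or trend fitting, and leaving out each repeat in turn.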

Results

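R1 is a mouse embryonic stem (ES) cell line of strain 129. Total RNA from 3 biological repeats of the line was hybridised to the Affymetrix Mouse Gene 1.0 ST array, which reads each transcript with probes placed along its exons. The 3 arrays form 1 group with no second condition, so the values answer which genes gave signal in these cells and how far the repeats differed from one another. Median probe set intensity was 47.8, 46.7 and 46.8 in repeats 1, 2 and 3, and the highest intensities were 15203, 15056 and 14061. The number of arrays limits the precision of every value. Gene values are given as log2 intensity, mean ± SD over the 3 repeats, and the background cutoff lay at 4.72, 4.60 and 4.61 in repeats 1, 2 and 3.

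The first question was which genes of the pluripotent state gave signal. All 18 measured genes of the core pluripotency list lay above background on all 3 arrays. Pou5f1, Sox2 and Nanog, transcription factors at the centre of the ES cell network, read 11.77 ± 0.12, 10.78 ± 0.017 and 11.002 ± 0.20 (SD, n = 3). Sall4, a zinc finger factor of the same network, read 9.91 ± 0.12, and Dppa2 had the list's largest SD, at 9.80 ± 0.25. All 11 measured naive pluripotency genes were above background as well, with Esrrb at 10.13 ± 0.057, Klf2 at 8.84 ± 0.17, Klf4 at 9.33 ± 0.087, Klf5 at 10.10 ± 0.024 and Fgfbp1 at 5.18 ± 0.40. The 10 measured genes of the formative and primed epiblast, the later states of the same lineage, gave signal too. Among them Fgf5 read 6.37 ± 0.40, Otx2 8.65 ± 0.38, Pou3f1 6.31 ± 0.20 and the de novo DNA methyltransferase Dnmt3b 8.88 ± 0.40. In a two-sided Fisher's exact test against all other genes outside the receptor families, Benjamini-Hochberg adjusted over 31 lists, the core list had a higher share above background (adjusted p = 0.0213). The naive and formative lists did not pass (adjusted p = 0.0909 and 0.118), although all of their measured members were above background. They passed at the 99th percentile of the receptor families (adjusted p = 0.0468 for both), and the naive list also with other silent families as background (0.0245). A list with all members above background can rise no further, so its p depends on its number of genes. Such lists of 8, 9 and 10 genes had an unadjusted p of 0.115, 0.0682 and 0.0721 in Fisher's exact test. They could not pass at the main cutoff, so a failure there is no difference from the core list.

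Signalling and proliferation genes gave signal throughout. All 26 genes of the LIF, BMP, WNT, FGF and Nodal list were above background, including the LIF receptor chains Lifr (8.97 ± 0.080) and Il6st (8.99 ± 0.075), the kinase Jak1 (8.21 ± 0.26) and the factor Stat3 (8.92 ± 0.11). Lefty1, a secreted inhibitor of Nodal, read 6.62 ± 1.00 and was the least even of them. All 19 proliferation genes were above background, among them Mki67 at 9.55 ± 0.10, Top2a at 7.44 ± 0.13, Ccna2 at 10.23 ± 0.026, Ccne1 at 10.53 ± 0.12 and Ccnd1 at 9.85 ± 0.36. Of 57 ribosomal protein genes 56 gave signal, with Rpl10 at 12.60 ± 0.039, Rpl10a at 11.88 ± 0.043 and Rpl12 at 8.83 ± 0.080; the exception was Rpl3l, at 4.36 ± 0.059. The paralogs Rpl10l (9.05 ± 0.16) and Rpl39l (6.48 ± 0.30) resemble their parent genes and are uncertain. The share above background was higher than among other genes for signalling (Fisher's exact test, adjusted p = 0.00373), proliferation (adjusted p = 0.0213) and ribosomal proteins (adjusted p = 5.16e-06).

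Chromatin and metabolic genes were also widely detected, but no list of them passed the test at the main background cutoff. Where all members were above background, the p again depended on list size. The 14 Polycomb genes were all above background (adjusted p = 0.0561), with the histone methyltransferase Ezh2 at 10.17 ± 0.023, Eed at 7.10 ± 0.15, Suz12 at 10.46 ± 0.12, Jarid2 at 11.16 ± 0.048 and Mtf2 at 11.11 ± 0.21. All 9 DNA methylation genes gave signal (adjusted p = 0.118), including Dnmt1 at 9.84 ± 0.11, Dnmt3a at 7.94 ± 0.17 and the cofactor Dnmt3l at 9.96 ± 0.11. Of 16 chromatin remodelling genes 15 gave signal (adjusted p = 0.109), with Smarca4 at 9.35 ± 0.052, Smarcc1 at 10.11 ± 0.13, Smarcd1 at 9.11 ± 0.13 and Smarcb1 at 9.39 ± 0.060. The exception was Smarca2, an alternative ATPase subunit of the same complexes, at 4.43 ± 0.12. All 13 genes of glycolysis and threonine catabolism were above background (adjusted p = 0.067), with Hk1 at 9.73 ± 0.075, Hk2 at 10.005 ± 0.054, Pfkl at 9.60 ± 0.077, Pfkp at 10.38 ± 0.053 and the glucose transporter Slc2a3 at 12.17 ± 0.12. All 10 genes of telomere maintenance and homologous recombination gave signal (adjusted p = 0.118), among them Tert at 6.03 ± 0.089, Terf1 at 10.49 ± 0.15, Terf2 at 7.31 ± 0.082, Rif1 at 10.68 ± 0.12 and Brca2 at 8.10 ± 0.18. Of 30 histone genes 24 gave signal (adjusted p = 0.563), and their near-identical copies leave single members such as H1f1 (10.43 ± 0.14), H1f10 (7.76 ± 0.27), H1f2 (7.29 ± 0.087), H1f3 (4.62 ± 0.20) and H4c3 (7.10 ± 0.45) uncertain. At the 99th percentile of the receptor families and with other silent families as background, the test was passed by Polycomb (adjusted p = 0.00127 and 4.75e-05), chromatin remodelling (0.0048 and 0.000108), glycolysis (0.00175 and 7.87e-05) and telomere maintenance (0.0081 and 0.00955). DNA methylation passed only with the other silent families (0.0138).

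Stress, growth control and reference genes were mostly detected. All 13 immediate early genes gave signal (adjusted p = 0.067), with Fos at 7.54 ± 0.38, Fosb at 7.35 ± 0.32, Jun at 6.93 ± 0.13 and Junb at 6.71 ± 0.12. The 11 heat shock and unfolded protein genes were all above background (adjusted p = 0.0909), among them Hspa8 at 12.47 ± 0.12, Hsph1 at 9.90 ± 0.15, Dnajb1 at 7.90 ± 0.074 and Chac1 at 6.38 ± 0.45; Hspa1a, at 5.95 ± 0.16, has a near-identical copy and is uncertain. All 8 p53 targets gave signal (adjusted p = 0.179), with Mdm2 at 9.65 ± 0.083, Ccng1 at 11.06 ± 0.092, Trp53inp1 at 10.42 ± 0.046, Sesn2 at 9.26 ± 0.023 and Bbc3 at 6.10 ± 0.21. Of 10 hypoxia genes 9 were above background (adjusted p = 0.422), with Vegfa at 7.65 ± 0.14, Bnip3 at 8.30 ± 0.056, Ankrd37 at 6.12 ± 0.022 and Egln3 at 7.32 ± 0.32, while carbonic anhydrase Car9 was not (4.18 ± 0.056). Of 6 CDK inhibitors 5 gave signal (adjusted p = 1), among them Cdkn1b (5.91 ± 0.25), Cdkn1c (7.05 ± 0.23), Cdkn2a (5.83 ± 0.085) and Cdkn2b (6.47 ± 0.059), and Cdkn2c did not (3.34 ± 0.021). All 13 imprinted genes gave signal (adjusted p = 0.067), including Igf2 at 7.28 ± 0.32, Peg3 at 7.62 ± 0.11, Meg3 at 9.47 ± 0.20, Dlk1 at 7.05 ± 0.18 and Plagl1 at 6.67 ± 0.49. All 9 housekeeping genes did so as well (adjusted p = 0.118, Fisher's exact test as above), with Actb at 12.96 ± 0.0019, Tbp at 8.34 ± 0.041, Ppia at 12.33 ± 0.044, Pgk1 at 11.53 ± 0.032 and Gusb at 6.20 ± 0.15. None of these lists passed at the main cutoff, where the p of a list with all members above background depended on its size. At the 99th percentile and with other silent families, the test was passed by immediate early (adjusted p = 0.02 and 0.00955), p53 (0.0208 and 0.0451), imprinted (0.00175 and 7.87e-05) and housekeeping genes (0.0139 and 0.0138). Heat shock (0.0048) and hypoxia genes (0.0468) passed at the 99th percentile only.

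Hox genes, genes of definitive endoderm derivatives and the few measured genes of the 2-cell-like state were less often detected than other genes. Of 37 Hox genes, the patterning factors of the body axis, 16 were above background on all 3 arrays (43.2%), and Hoxa11 (3.72 ± 0.097), Hoxa13 (4.54 ± 0.027) and Hoxa2 (4.13 ± 0.049) were not; Hoxa10 (4.77 ± 0.18) and Hoxc8 (4.81 ± 0.33) passed the cutoff on 2 arrays. Of 10 genes of definitive endoderm derivatives 3 gave signal, namely Cdx1 (6.17 ± 0.18), Nkx2-1 (4.97 ± 0.044) and Vil1 (4.999 ± 0.093), while Pdx1 (4.42 ± 0.058), Alb (3.37 ± 0.075), Neurog3 (4.06 ± 0.13) and Sftpc (3.99 ± 0.24) did not. The list for the 2-cell-like state was written with 14 genes, of which 4 were measured, so the others were not read. None of the 4 was above background on all 3 arrays, with Usp17la at 3.18 ± 0.16, Usp17lc at 4.31 ± 0.21, Zfp352 at 4.56 ± 0.24 and Tdpoz1 at 3.96 ± 0.27. These families hold near-identical copies. The share was lower than among other genes for Hox (Fisher's exact test, adjusted p = 0.00373), definitive endoderm derivatives (adjusted p = 0.0348) and the 2-cell-like state (adjusted p = 0.0343). The Hox call was lost when 2 of the 3 arrays sufficed (adjusted p = 0.0726). The 2-cell-like call was lost at the 99th percentile of the receptor families (adjusted p = 0.0634) and with other silent families as background (adjusted p = 0.185).

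Lists of early lineages gave signal at shares close to those of other genes, and none passed Fisher's exact test. Of 12 primitive streak genes 10 were above background (adjusted p = 0.642), with Mixl1 at 5.41 ± 0.020, Eomes at 6.28 ± 0.17 and Gsc at 5.98 ± 0.14, while Evx1 (4.51 ± 0.064) and Mesp1 (4.46 ± 0.38) were not on all 3 arrays. Of 17 primitive and visceral endoderm genes 13 gave signal (adjusted p = 0.877), including Gata6 at 5.93 ± 0.17, Gata4 at 6.06 ± 0.11, Sox7 at 5.07 ± 0.082 and Cubn at 5.59 ± 0.48. Sox17 (4.60 ± 0.076), Dab2 (4.50 ± 0.059), Afp (3.79 ± 0.071) and Ttr (3.50 ± 0.17) did not. Of 12 trophoblast genes 9 gave signal (adjusted p = 1), with Cdx2 at 5.57 ± 0.16, Tfap2c at 7.56 ± 0.057, Hand1 at 5.74 ± 0.078 and Fgfr2 at 6.13 ± 0.30, and Elf5 (4.31 ± 0.10), Gata3 (4.77 ± 0.23) and the placental gene Tpbpa (2.91 ± 0.070) did not on all 3 arrays. Of 13 neuroectoderm genes 8 gave signal (adjusted p = 0.642), among them Sox1 at 6.88 ± 0.17, Pax6 at 5.16 ± 0.095 and Nes at 6.65 ± 0.28. Pax3 (4.61 ± 0.029), Neurod1 (4.82 ± 0.46), Neurog2 (4.23 ± 0.070), Zic1 (4.31 ± 0.12) and Gfap (4.43 ± 0.16) were not above background on all 3 arrays. Of 14 genes of mesoderm derivatives 10 gave signal (adjusted p = 1), with Nkx2-5 at 6.66 ± 0.14, Myod1 at 5.46 ± 0.089, Myog at 4.66 ± 0.075 and Runx1 at 5.85 ± 0.27. Tbx5 (3.96 ± 0.071), Meox1 (4.32 ± 0.058), Hbb-bh1 (2.76 ± 0.082) and Cdh5 (4.52 ± 0.11) did not on all 3 arrays. With other silent families as background the cutoff lay higher, at 6.01, 6.23 and 6.17 in repeats 1, 2 and 3. Of the genes named here as giving signal, only Eomes, Tfap2c, Sox1, Nes and Nkx2-5 exceeded it on all 3 arrays. Signal of the others is therefore near background and was not shown to be expression. The same holds for Fgfbp1, Cdkn1b, Cdkn2a, Nkx2-1 and Vil1, named earlier, which lay below this higher cutoff on all 3 arrays. Fgf5, Pou3f1, Lefty1, Tert, Hspa1a, Ankrd37, Chac1, Bbc3, Gusb and Cdx1, also named earlier, exceeded it on some arrays only.

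Markers of other cell types were also read. Of 17 fibroblast markers 15 were above background (adjusted p = 0.264), with the collagens Col1a1 at 8.71 ± 0.36, Col1a2 at 8.18 ± 0.29 and Col3a1 at 7.197 ± 0.25, Thy1 at 7.11 ± 0.21 and smooth muscle actin Acta2 at 8.25 ± 0.79; Lum (4.37 ± 0.20) and S100a4 (4.85 ± 0.26) were not on all 3 arrays. Of 15 germline genes 12 gave signal (adjusted p = 0.663), including the RNA helicase Ddx4 at 6.78 ± 0.39, Dazl at 6.79 ± 0.47, Sycp3 at 6.84 ± 0.33 and Stra8 at 5.41 ± 0.66, and Sycp1 (4.12 ± 0.20), Nanos2 (4.07 ± 0.076) and Piwil1 (4.21 ± 0.16) did not. Of 11 haematopoietic and immune genes 4 gave signal (adjusted p = 0.0561), namely Cd3e (5.504 ± 0.18), Laptm5 (8.98 ± 0.23), Cd68 (7.33 ± 0.11) and Coro1a (6.42 ± 0.038), while the pan-leukocyte gene Ptprc (3.70 ± 0.030), Cd79a (3.52 ± 0.085) and Lyz2 (3.69 ± 0.14) did not. Of 10 interferon response and antigen presentation genes 6 gave signal (adjusted p = 0.627), with B2m at 7.65 ± 0.67, Tap1 at 5.77 ± 0.14 and Nlrc5 at 5.29 ± 0.087. Psmb8 (4.78 ± 0.21), Ifit1 (4.48 ± 0.72), Ifih1 (4.42 ± 0.27) and Tlr3 (3.37 ± 0.15) did not on all 3 arrays. Cd3e, Stra8, Tap1 and Nlrc5 fell below the cutoff set by other silent families on all 3 arrays, so their signal is near background. Fibroblast markers passed the test with a higher share at the 99th percentile (adjusted p = 0.0468) and with other silent families (0.0138). Haematopoietic genes passed it with a lower share when 2 of 3 arrays sufficed (0.0456). Over all genes, 12825 of 19057 (67.3%) lay above background on all 3 arrays, 775 on some arrays and 5457 on none, and 7716 did so when other silent families set the background. Lists with a higher share numbered 4 and lists with a lower share 3, and the former became 17 at the 99th percentile and 15 with the other silent families.

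**Figure D1:**
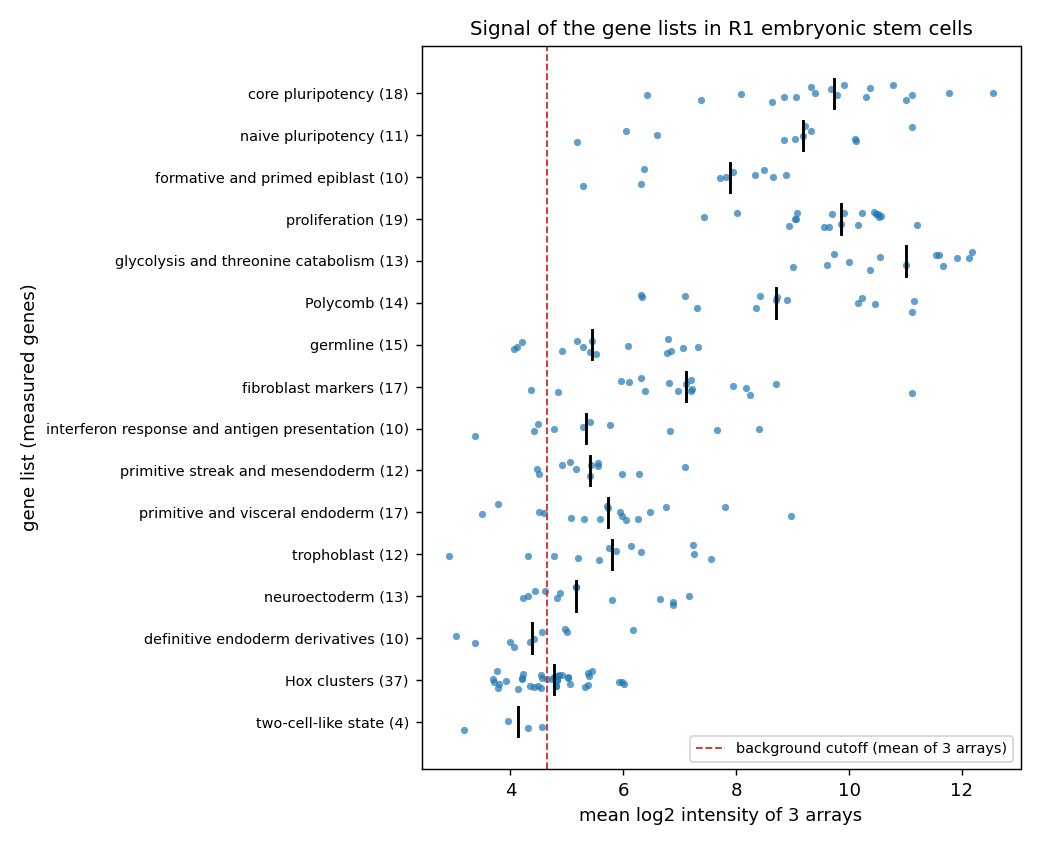
Mean log2 intensity of 3 arrays (horizontal axis) for the genes of 16 lists (vertical axis, measured genes in brackets); each point is a gene, the black bar is the list's median and the dashed line is the mean background cutoff. All 18 core pluripotency genes lie to the right of the cutoff, while 16 of 37 Hox genes passed it on all 3 arrays; intensities of different probe sets are not compared with one another.

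The second question was how far the repeats differed. Among genes above background the median SD was 0.101 log2 units and the 90th percentile 0.209. Interferon-induced Irgm1 spread over 2.05 log2 units, the Nodal inhibitor Lefty1 over 1.97, the activin subunit Inhba over 1.92 and Acta2 over 1.54. In all, 36 genes above background on all 3 arrays spanned more than 1 log2 unit, and in 29 of them repeat 2 lay farthest from the median and higher. Repeat 2 was farthest and lower in 3 genes, and repeat 3 was farthest and lower in 4. Across genes, which are not independent replicates, Pearson's r was 0.992 between repeats 1 and 2, 0.994 between 1 and 3 and 0.991 between 2 and 3. Of genes above background on all 3 arrays, 24, 0 and 28 lay more than 2-fold apart in these pairs. No gene above background on all 3 arrays passed the threshold once repeat 2 was left out.

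Genes that varied beyond the trend were mostly higher in repeat 2. Irgm1 was 1.90 log2 units above the mean of the other repeats (3.72-fold), Inhba 1.64 (3.11-fold) and B2m, the light chain of MHC class I, 1.13 (2.18-fold). Acta2 lay at 1.29 (2.44-fold), the collagen cross-linking enzyme Lox at 1.35, thrombospondin Thbs1 at 1.15 and the metalloproteinase inhibitor Timp3 at 1.16. Anxa1 (1.19), Ifi27 (1.30), Lgals9 (1.24) and 9330159F19Rik (1.28) were higher in repeat 2 too, while Lefty1 fell by 1.61 there and Olfr767, of the receptor families that set the background, fell by 1.21. The ubiquitin-like protease gene Usp18 and Rtp4 were higher in repeat 2 too, but each was above background on 2 arrays, so no difference is given. The same holds for 1810037I17Rik, which was lower in repeat 1. Gm5662, Gm7982, Gm5039 and Tdpoz3, higher in repeat 2, were above background on 1 or 2 arrays and belong to families with near-identical copies. Zbtb10 (-0.98) and Nab2 (-0.91) were lower in repeat 3. The limma variance test with Benjamini-Hochberg adjustment called 22 of 13600 genes, with adjusted p from 0.0006 for Gm5662 to 0.0458 for Nab2, and 782 had an unadjusted p under 0.05. Of the 22, 15 were above background on all 3 arrays, and repeat 2 was farthest and higher in 17 and farthest and lower in 2. The count was 0 without repeat 1, 34 without repeat 2 (5 of them among the 22) and 11 without repeat 3, and it was 13 after quantile normalization, 10 without the robust prior and 1 without the trend. Without repeat 2 the prior degrees of freedom were infinite, against 9.85 with all repeats. The 34 is therefore not comparable with the 22.

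**Figure D2:**
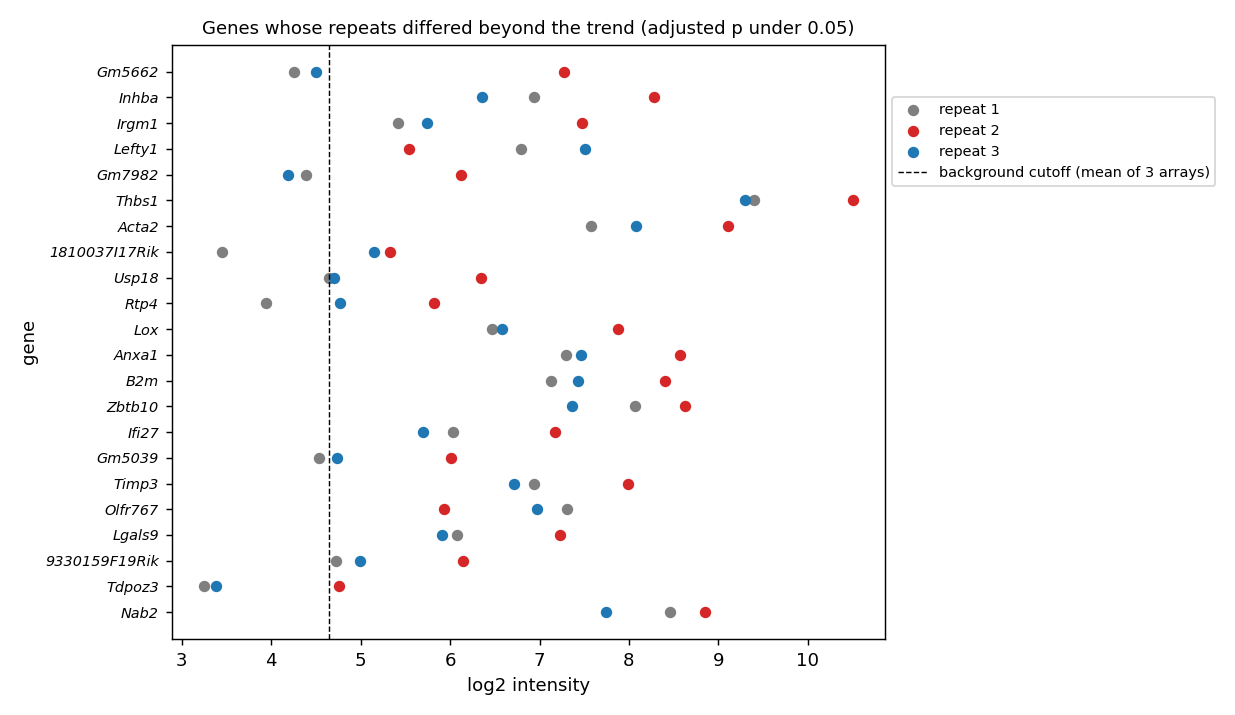
Log2 intensity (horizontal axis) of the 22 genes called by the variance test (vertical axis); each point is 1 repeat and the dashed line is the mean background cutoff of the 3 arrays. Repeat 2 lies apart and higher in 17 genes, such as Irgm1 and Inhba, and apart and lower in 2, Lefty1 and Olfr767.

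Some gene lists differed between repeats more than random lists of the same mean level did. The median SD was 0.2997 for the formative list, 0.276 for interferon genes, 0.255 for fibroblast markers, 0.208 for naive genes and 0.205 for germline genes, against 0.098, 0.108, 0.102, 0.086 and 0.111 in matched lists. It was 0.132 for signalling against 0.093, and 0.224 for the 4 genes of the 2-cell-like state, all near background, against 0.109. Against 10000 random lists the adjusted empirical p was 0.00155 for the naive, formative, fibroblast and interferon lists (unadjusted p = 0.0002, the smallest they can give). It was 0.00248 for germline and 0.0487 for both signalling and the 2-cell-like state. This p sets a list against other genes on the same arrays and does not measure variation over further repeats. The signalling call was lost after quantile normalization (0.125), with the highest probe set (0.0566) and without repeat 3 (0.251), and the 2-cell-like spread changed direction without repeat 3 (0.992). The other 24 lists did not pass, so none was called for a smaller spread; ribosomal proteins, at 0.060 against 0.075, were called so after quantile normalization (adjusted permutation p = 0.00207), which also called immediate early genes for a larger spread (0.0151). Unadjusted p under 0.05 was reached by 10 lists with a larger spread and 0 with a smaller one. Without repeat 2 no list passed. Without repeat 1, 11 lists passed with a larger spread and 1, ribosomal proteins, with a smaller one (adjusted permutation p = 0.00372). The lists called there and not with all repeats were Polycomb (0.0093), DNA methylation (0.0367), immediate early (0.0231), imprinted (0.0062) and ribosomal proteins. Without repeat 3, 5 lists passed with a larger spread; random lists ignore that genes of a pathway vary together.

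In repeat 2 several gene groups lay apart from the other repeats. Interferon and antigen presentation genes had a median 0.45 log2 units above the mean of the other repeats (1.37-fold, 7 of 10 genes higher), with B2m at 1.13; Ifit1 was above background in repeat 2 alone. Fibroblast markers lay at 0.39 (1.31-fold, 15 of 17 higher), with Acta2 at 1.29, Col1a1 at 0.61 and Col1a2 at 0.50, while Lum and S100a4, not above background on all 3 arrays, were not higher. Germline genes lay at 0.30 (1.23-fold, 14 of 15 higher), with Stra8 at 1.13, Dazl at 0.74 and Ddx4 at 0.66. Naive genes lay at 0.25 (8 of 11 higher), while Klf2 (-0.29), Klf4 (-0.07) and Klf5 (-0.04) were lower. Formative genes lay at -0.49 (0.711-fold, 9 of 10 lower), with Dnmt3b at -0.67, Fgf5 at -0.67 and Otx2 at -0.65. Fibroblast markers were therefore higher in the same repeat as the interferon, germline and naive groups, and formative genes were lower there. The core pluripotency list, at -0.02, stayed within the middle 95% of random lists.

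Other lists also lay apart in repeat 2. Polycomb at 0.17 and histones at 0.13 lay above the middle 95% of random lists. DNA methylation at -0.11, immediate early genes at -0.11, telomere maintenance at -0.08, proliferation at -0.06 and glycolysis at -0.05 lay below it. In repeat 1 the formative list lay above the range (0.21), and germline (-0.13), interferon (-0.24) and primitive endoderm (-0.10) genes lay below it. In repeat 3 the formative (0.23), DNA methylation (0.18), p53 (0.12) and ribosomal (0.04) lists lay above it. The signalling (-0.09), trophoblast (-0.16), germline (-0.21), fibroblast (-0.27), interferon (-0.26) and histone (-0.07) lists lay below it. The 2-cell-like list lay above the range in repeat 2 and below it in repeat 3, but none of its 4 genes was above background on all 3 arrays, so no difference is given. In all, 28 of 93 values lay outside, against 4.65 expected for independent genes. The shifts of a gene over the 3 repeats sum to 0, and a shift of 1 array against 2 has no replicate check and no p-value.

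Single members of these lists passed the limma variance test more often when adjusted over the list alone than over all genes. The smaller number of tests largely ensures this, and no correction was made across the lists. The genes named here were chosen after their values were seen. Adjusted over the list alone, 7 fibroblast markers passed (Col1a1, Col1a2, Postn, Prrx1, Acta2, Tagln and Timp3), against 2 over all genes. In the germline list 7 passed (Ddx4, Dazl, Sycp3, Stk31, Slc25a31, Hormad1 and Stra8), against 0. In the formative list 6 passed (Fgf5, Otx2, Dnmt3b, Lef1, Cldn6 and Fgf15), against 0. Among interferon genes 5 passed (B2m, Irf7, Ifit1, Oas1a and Ddx58), against 1. In the naive list 4 passed (Tbx3, Tfcp2l1, Zfp42 and Fgfbp1), against 0, and in the signalling list 3 (Spry4, Lefty1 and Lefty2), against 1. Immediate early genes gave 3 (Fos, Fosb and Myc) and heat shock genes 2 (Trib3 and Chac1), each against 0. Cubn, Neurod1, Dnmt3b, Ccnd1, Plagl1 and H4c3 were the 1 gene passing in the primitive endoderm, neuroectoderm, DNA methylation, proliferation, imprinted and histone lists. Of the genes named here, Ifit1 and Neurod1 were not above background on all 3 arrays. No member of the other 17 lists passed by either adjustment.

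**Figure D3:**
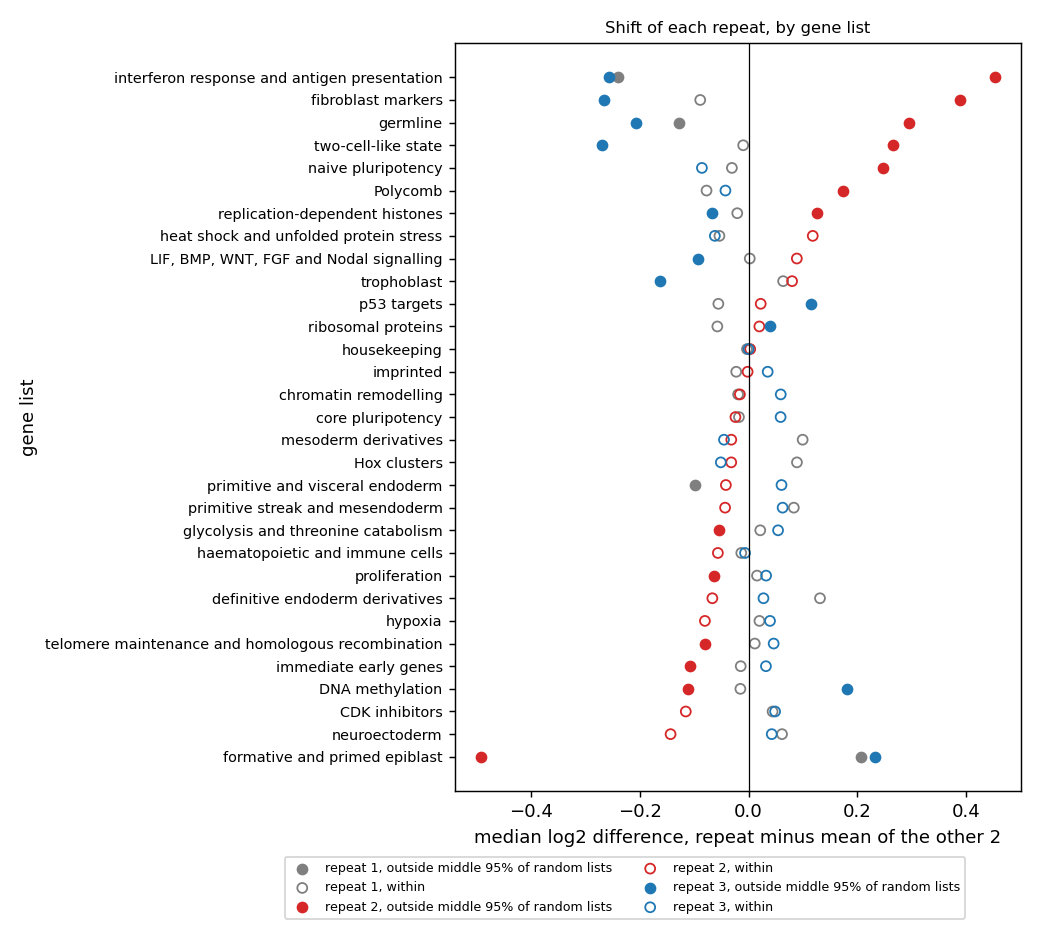
Median log2 difference between each repeat and the mean of the other 2 (horizontal axis) for 31 gene lists (vertical axis); filled points lie outside the middle 95% of level-matched random lists and open points within it. Repeat 2 spans -0.49 for the formative list to 0.45 for the interferon list.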

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

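No test was made for the values in this part, which come from probe sets that enter no comparison of the report. Signal above the background cutoff on all 3 arrays was seen in 2174 of 4547 probe sets with no gene in the annotation (47.8%). Their median SD between repeats was 0.122, and 34 spanned more than 1 log2 unit. Of 1419 probe sets that name several genes, 868 (61.2%) were above the cutoff on all 3 arrays, with a median SD of 0.083. No gene was named from either kind, and no explanation was tested. Outliers among the repeats were not tested because a group of 3 is too small for that test, and with 1 group there are no effects to set against each other.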

How the results depend on the processing

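All alternatives were planned before the data were examined. The group holds 3 repeats and no second condition, so no paired analysis was possible because there is only 1 group. The 28 list shifts outside the random range kept their direction and moved by less than the median SD of the list's own genes between repeats in all 82 alternatives. These were quantile normalization, genes above background only and the highest probe set, with no repeat left out. Whether each shift stayed outside the random range was not part of this check. The called lists above background kept their call in 53 of 56 alternatives, and 15 further lists were called only under an alternative. The exceptions were Hox when 2 of 3 arrays sufficed (adjusted p = 0.0726) and the 2-cell-like list at the 99th percentile (0.0634) and with other silent families (0.185). With those families 7716 genes were above background against 12825, and the lists with a higher share rose from 4 to 15, and to 17 at the 99th percentile, since fewer genes outside the lists then passed. Genes spanning more than 1 log2 unit numbered 0 to 32 with 1 repeat left out, against 36. Lists with a larger spread numbered 0 to 11 with 1 repeat left out, against 7, and lists with a smaller spread 0 to 1, and 1 after quantile normalization, against 0. Over the 3 left-out repeats the adjusted spread p ran from 0.00542 to 0.244 for naive genes, 0.00155 to 0.244 for formative, 0.00443 to 0.537 for signalling, 0.0031 to 0.992 for the 2-cell-like list, 0.00155 to 0.75 for germline, 0.00155 to 0.217 for fibroblast markers and 0.00155 to 0.924 for interferon genes. The highest value came without repeat 2, except for the 2-cell-like list, whose direction reversed without repeat 3; signalling also lost its call without repeat 3 (0.251), after quantile normalization (0.125) and with the highest probe set (0.0566). The 2-cell-like list has no value among genes above background, where under 3 members were left. The limma variance test called 13 genes after quantile normalization, 10 without the robust prior, 1 without the trend and 0 to 34 with 1 repeat left out, against 22; 13, 10, 1, and 0, 5 and 11 without repeats 1, 2 and 3, were among the 22. Without repeat 2 its prior degrees of freedom were infinite, against 9.85 with all repeats, so that count is not comparable with the 22. Apart from this and the fewer arrays left after removing a repeat, the cause was not tested. Signal near the cutoff limits the 2-cell-like and Hox values.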

Other observations

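The tests of a lower share of ES cells and of other genes at the same signal level were chosen after the result was seen; the other tests used 6 further gene lists written before their own values were seen but after the earlier lists had pointed to repeat 2. A trend with signal level would move random lists of the same mean level about as far as the list itself. No biological explanation tied to a group was tested, because the design has 1 group.

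The further lists gave a mixed picture of repeat 2. A second interferon list of 16 genes lay at a median of 0.25 log2 units above the other repeats (95% bootstrap interval 0.20 to 0.58 over genes), with Usp18 and Rtp4 (both also called by the variance test), Parp14 (0.70) and Gbp3 (0.72) among its higher members and Ifit3 and Ifit2 near background. A second fibroblast list of 15 genes lay at 0.33 (0.19 to 0.44), and 10 contractile and matricellular genes lay at 0.30 (0.15 to 0.51). A second naive list of 7 genes lay at 0.18 (0.04 to 0.35). A second germline list of 12 genes, 6 of them higher, lay at 0.11, with an interval of -0.08 to 0.27 that spans 0. The second formative list of 10 genes lay at -0.06 (-0.23 to 0.19), so the lower formative signal did not extend to it: Zic5 lay at -0.33 but Ccnd2 at 0.65.

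Interferon genes were higher in repeat 2. A trend with signal level is argued against by the second list, at percentile 100 among lists of the same mean level; the earlier list, at 0.45 against -0.031 log2 units in such lists, was too variable to decide alone (bootstrap SE 0.29). A larger share of feeder fibroblasts, which the labels do not mention, may account for part of it, but was not told apart from a separate interferon change. The second interferon list differed from the second fibroblast list by -0.071 log2 units (bootstrap SE 0.12), within the bound set beforehand. A separate interferon change of like size would meet that bound too. The feeder reading also stays open because fibroblast markers well above background moved unevenly, with Dcn at 0.10 and Fn1 at 0.10 against Col1a1 at 0.61 and Acta2 at 1.29. Dcn and Fn1 were chosen after their values were seen. Irgm1, at 1.90, exceeded all of these, but it was picked for the largest SD among genes above background, so this decides nothing.

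Formative genes were lower in repeat 2. A lower share of ES cells as the whole cause would have lowered the core pluripotency list about as far. That list lay 0.47 log2 units above the formative list (bootstrap SE 0.13, over genes and not over arrays), which argues against it. The shifts of these lists were already known when this comparison was chosen. A small fall in the share of ES cells is not excluded. The core list lay at -0.024 against 0.033 in random lists of the same mean level (percentile 3.58). Other genes of the same signal level did not share the fall. Random lists of the same mean level lay at 0.029 log2 units against -0.49 for the formative list (bootstrap SE 0.12). The formative list lay at -0.54 after quantile normalization. It was already known to lie outside such random lists when this comparison was chosen, so a trend with signal level was not tested separately. The second list, which barely shifted, lay at percentile 6.6, inside the bound set beforehand for a trend. A shift from formative towards naive expression could not be settled by the further lists, whose difference was 0.25 (bootstrap SE 0.16). The pattern may concern only genes of the earlier list, such as Fgf5, Otx2 and Dnmt3b.

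Germline genes were higher in repeat 2. Other genes of the same signal level did not share the rise, lying at -0.027 log2 units against 0.30 for the germline list (bootstrap SE 0.12). The germline list lay at 0.31 after quantile normalization. It was already known to lie outside random lists of the same mean level when this comparison was chosen, so a trend with signal level was not tested separately. The second list lay at percentile 98.68, past the bound set beforehand against a trend. It does not settle the question, since 6 of its 12 genes were higher and its interval spans 0. Whether a larger share of feeder fibroblasts could be the cause stays open, since the second germline list lay -0.21 from the fibroblast list (bootstrap SE 0.15) and was not clearly shifted itself.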
